A study of Drosophila melanogaster with 2 samples.

How the data were processed

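The series holds small RNA libraries from testes of wild-type flies, 1 per age, and each age is a group by the labels. Per the labels' protocols, total RNA was isolated with TRIzol, and RNA of 19 to 28 nt was cloned and sequenced on an Illumina instrument. The authors deposited a table per library in which each line holds a distinct sequence, its length, a single annotation name and its reads. The reads are raw counts in whole numbers, per the file headers, and were not normalized. The deposited length was checked and equals the length of the sequence in every line. The submitters' processing notes name genome build dm3. The aligner, the mismatch setting and the order in which names were given to reads are not given in the sources used here, and the tables hold no genome positions. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, which is 0.250 RPM at 1 day and 0.258 RPM at 30 days.

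Both tables were joined by sequence, and no sequence had different names in the libraries. Names were sorted into classes, namely miRNA, hairpin siRNA, transposon, Su(Ste), structural RNA, other noncoding RNA, rRNA pseudogene, transcript, mitochondrial mRNA, other repeat and no name. Structural RNA was recognised by its name or by the biotype of the gene in the BDGP6 annotation and the RefSeq gene table, and the 7SL and snmRNA names were included. Of 69 noncoding names ending in a CR number 30 matched the gene table, and the rest stayed among other noncoding RNA. rRNA pseudogenes stayed in. All reads but structural RNA, 12004233 at 1 day and 11642019 at 30 days, formed the denominator of RPM (reads per 1000000).

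The plan for miRNA reads needed a genome, so it was adapted to the deposited names. For each named arm the most frequent sequence over both libraries gave the reference 5′ end. A read belonged to an arm when it overlapped this sequence exactly by at least 15 nt and began within 2 nt of its 5′ end. Reads with the name of a hairpin but of no arm were assigned in this way and were 1.07% of miRNA reads, and 99.8% of miRNA-named reads lay within 2 nt. A miRNA made by several hairpins is uncertain in its source. Repbase and FlyBase spellings of a transposon family were merged by a table of aliases written after the names were seen, which gave 153 families from 7019 names. Each sequence has a single name, so reads shared by families could not be split, and counts of related families are uncertain. Transcript reads were summed by gene symbol over introns, UTRs and coding parts. Positions of hairpins and genes come from the BDGP6 annotation by name and are not those of build dm3.

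The ratio of 30-day to 1-day RPM has the exact conditional (Clopper-Pearson) 95% interval, and a share of a library has the exact binomial interval. With 1 library per group no p-value is given. The thresholds, the lists of miRNAs, transposons and niche genes and the rule for named items were fixed before the data were examined. An item is called at a ratio of at least 2 or at most 0.5 with an interval that excludes 1. Calls were counted among miRNA arms with at least 100 reads and transposon families with at least 1000 reads over both libraries. An item with 0 reads at 1 day has no ratio and could not be called higher. In contrast 0 reads at 30 days could give a call of lower. Named items are both arms of let-7, miR-100 and miR-125, the 10 largest and 10 smallest miRNA ratios, the 5 most abundant miRNAs, the 5 largest and 5 smallest transposon ratios and the 3 most abundant families, each hairpin siRNA and piRNA source locus that could be located, upd1 and Imp, and at most 4 members of each list with the largest change. Remaining members of small lists and of the niche list, single siRNAs, and items in the closing section beyond these were named after their values were seen. For a list of miRNAs the most abundant arm of each hairpin was used. A list with at least 3 measured members was set against 10000 random lists, each member drawn from a window of the 20 features nearest to it in total reads and itself. Lists of mRNA markers (larval and adult fat body, accessory gland, midgut, flight muscle, spermatid, germline, neural, blood cell, housekeeping and ribosomal protein genes) were written after part of the values had been seen.

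Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and edgeR 4.0.16 in R 4.3.3 gave the TMM factors. The rule was tested on simulated Poisson counts for 4321 miRNA arms and genes in the comparison of 30-day with 1-day testes, 200 of them changed. Of 134 features changed 3-fold or 5-fold 98.5% were called in the right direction. Of 66 changed 1.5-fold 1 was called, and of 4121 unchanged features none was. The true ratio lay in 95.7% of the intervals of unchanged features. Of 100 unchanged random lists 2 fell outside the central 95% of percentiles, and all 100 lists of features raised 3-fold or 5-fold lay above it. Simulated counts hold no variation between libraries. Their lists were also ranked among arms and genes together, 4121 of 4321 unchanged and all drawn independently. How often a list of real arms or families gives an extreme percentile was therefore not measured.

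The alternatives tried were other denominators (all reads, miRNA reads, TMM over miRNAs, transposon reads), the 5′ end of miRNA reads exact or any overlap of 15 nt, minimums of 10 and 1000 reads for miRNAs and 100 for transposons, lengths of 24 to 27 nt for piRNAs and 21 nt for siRNAs, structural RNA kept in or miRNA reads left out of the length share, and distinct sequences counted once. The deposited arm names as they stand and rRNA pseudogenes left out were added after seeing the data, as were the transposon scale for miRNAs, hairpin siRNAs and Su(Ste) and both scales for single genes, read classes and transposon reads of 21 nt.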

Results

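Small RNAs of 19 to 28 nt were sequenced from the testes of wild-type Oregon R flies at 2 adult ages, 1 day and 30 days, with 1 library per age. RNA came from 1005 young and 1018 aged males kept at 25 °C. The study asks how ageing affects the stem cell niche at the testis tip, and its title names the miRNA let-7 and the RNA-binding protein Imp. The 1-day library held 12041835 reads in 1780207 distinct sequences, and the 30-day library held 11706908 reads in 1816449 distinct sequences. There were no replicates, so no test between the ages was possible, and each ratio compares these libraries with an exact 95% interval given in parentheses. Abundance is in RPM, reads per 1000000 reads free of structural RNA, and ratios are 30-day over 1-day. An item was called higher or lower, and is said to rise or fall, where the ratio was at least 2 or at most 0.5 and the interval excluded 1. Ratios were also taken per 1000000 miRNA reads (the miRNA scale) and per 1000000 transposon reads (the transposon scale), which are named where they changed the direction or the call of a miRNA arm, transposon family, siRNA locus or gene given here.

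Most small RNAs of the testis are Piwi-interacting RNAs (piRNAs), which silence transposons, and miRNAs, which repress mRNAs, make up much of the rest. Reads named as transposons were 54.7% of all reads at 1 day and 47.6% at 30 days, and reads named as miRNAs were 23.2% and 31.6%. Reads of 23 to 28 nt, the length of piRNAs, made up 68.9% of the reads free of structural RNA at 1 day (exact binomial 95% interval 68.91 to 68.96%) and 65.7% at 30 days (65.67 to 65.72%). With miRNA reads left out the order of the ages reversed, to 76.0% at 1 day and 77.7% at 30 days. Structural RNA (rRNA, tRNA, snRNA and snoRNA) made up 0.312% of the reads at 1 day and 0.554% at 30 days. Of the distinct sequences 20.5% were read in both libraries, and these held 88.3% of the 1-day reads and 88.1% of the 30-day reads.

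**Figure D1:**
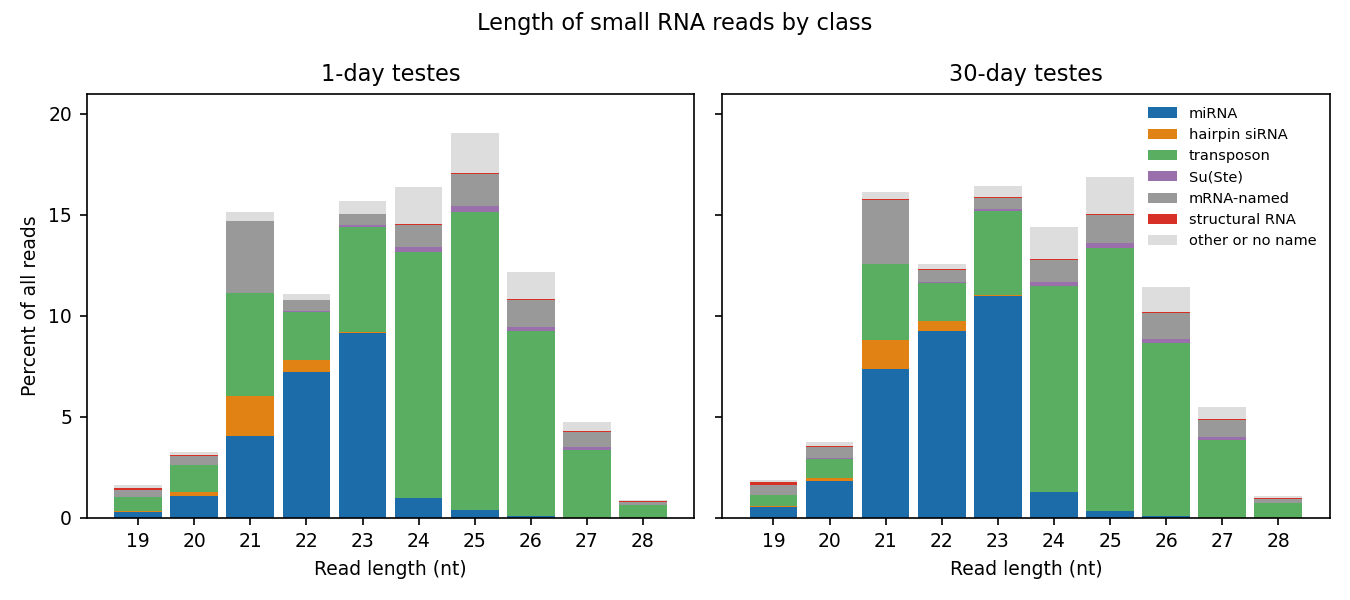
Percent of all reads (vertical axis) by read length in nt (horizontal axis) in the 1-day library (left) and the 30-day library (right), stacked by the class of the name each read carries. The miRNA reads were most frequent at 23 nt and made up 23.2% and 31.6% of all reads, and transposon reads were most frequent at 25 nt in both libraries.

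The miRNA let-7, named in the study's title, controls developmental timing and is processed from 1 primary transcript together with miR-100 and miR-125. Its mature arm let-7-5p (TGAGGTAGTAGGTTGTATAGT) was more abundant in the aged testis, and whether it passed the 2-fold line depended on the scale. It gave 9792 RPM at 1 day and 18693 RPM at 30 days, a ratio of 1.91 (1.90 to 1.92), from 117547 and 217624 reads. This was no call, the ratio was 1.40 on the miRNA scale, and it was 2.13 and a call on the transposon scale. miR-125-5p rose from 210.2 to 432.9 RPM, a ratio of 2.06 (1.963 to 2.161), which was 1.51 and no longer a call on the miRNA scale. miR-100-5p went from 88.1 to 176.0 RPM, and its ratio (1.85 to 2.15) lay just under 2, but was 2.23 and a call on the transposon scale. The hairpins lie on the plus strand of chromosome 2L, mir-100 at 18471434 to 18471533, let-7 at 18472034 to 18472111 and mir-125 at 18472315 to 18472424. These positions are from the BDGP6 annotation by name, because the deposited tables hold no coordinates.

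The opposite arms of these hairpins, named star in the deposited tables, rose by more than the mature arms. The let-7-3p star arm rose from 27 to 286 reads, a ratio of 10.9 (7.35 to 16.9). The miR-100-3p star arm rose 6.44-fold (5.86 to 7.09), to 3147 reads, more than the 2049 reads of miR-100-5p at that age. The miR-125-3p star arm rose 3.27-fold (2.49 to 4.34), from 70 to 222 reads. With the most abundant arm of each hairpin over both libraries, let-7-5p, miR-125-5p and the miR-100-3p star arm, the complex had a median ratio of 2.06. The star arm held 32.3% of the reads of both miR-100 arms at 1 day and 60.6% at 30 days. Its own rise thus placed it in this list, so it is no independent support for a rise of the complex. That median lay at percentile 89.8 of 10000 random lists of the same size matched on abundance, which is how percentiles are given for the lists that follow. Members of random lists were drawn independently, while hairpins of a cluster can share a transcript, as those of let-7 do. An extreme percentile of a cluster can thus come from a single shared change.

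Many more miRNAs rose than fell with age on the main scale. Of 173 arms with at least 100 reads, 48 were higher at 30 days, 4 were lower and 121 were neither. Of 66 star arms 30 were higher and 1 was lower, against 18 higher and 3 lower among the 107 remaining arms. The median log2 ratio over the 173 arms was 0.29. The miRNA scale shifted every log2 ratio by -0.45 and gave 25 higher and 11 lower arms, a TMM factor over miRNAs shifted them by -0.38 and gave 28 and 8, and the transposon scale gave 55 and 3. Higher arms were thus 92.3% of the calls on the main scale, 69.4% on the miRNA scale and 77.8% with TMM.

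**Figure D2:**
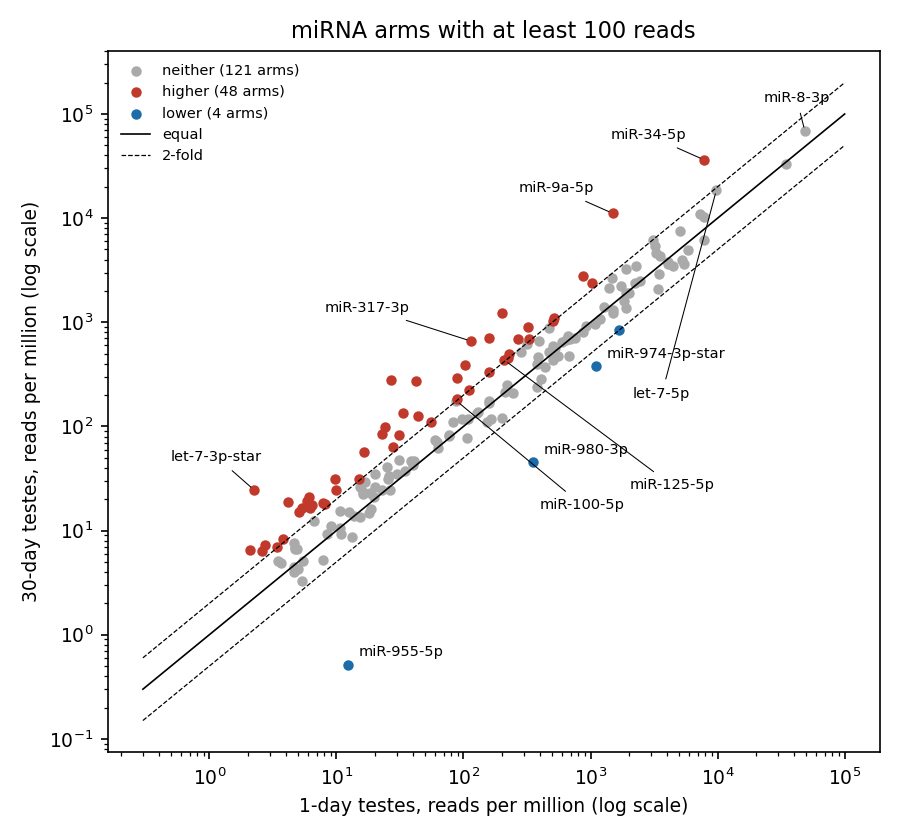
RPM of each of the 173 miRNA arms in the 1-day library (horizontal axis, log scale) and the 30-day library (vertical axis, log scale), 1 point per arm, with the line of equality and dashed 2-fold lines. The 48 arms called higher lie above the upper dashed line, miR-34-5p at 36256 RPM among them, and the 4 called lower lie below the other, while on the miRNA scale the counts were 25 and 11.

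miR-34, which is known to act in the ageing fly brain, and miR-9a stood out among abundant miRNAs. miR-34-5p (TGGCAGTGTGGTTAGCTGGTT) rose from 7845 to 36256 RPM, a ratio of 4.62 (4.59 to 4.65). miR-9a-5p rose from 1493 to 11130 RPM, a ratio of 7.45 (7.34 to 7.57), and its star arm rose 10.4-fold (9.26 to 11.7). Reads of miR-34-5p were also shorter at 30 days. Forms of 19 to 21 nt made up 38.6% of its reads at 1 day and 71.5% at 30 days, and the 24-nt form went from 20.2% to 7.24%. The mean length went from 22.1 to 21.3 nt. Only the share of the 24-nt form fell, while its abundance went from 1583 to 2624 RPM. That was a ratio of 1.66, against 7.91 for the 21-nt form. The remaining arms among the 10 with the largest ratios were the miR-284-5p star arm at 6.16, miR-317-3p at 5.77, the miR-317-5p star arm at 4.54, miR-33-5p at 4.44 and miR-87-3p at 4.08, all called higher on every scale.

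**Figure D3:**
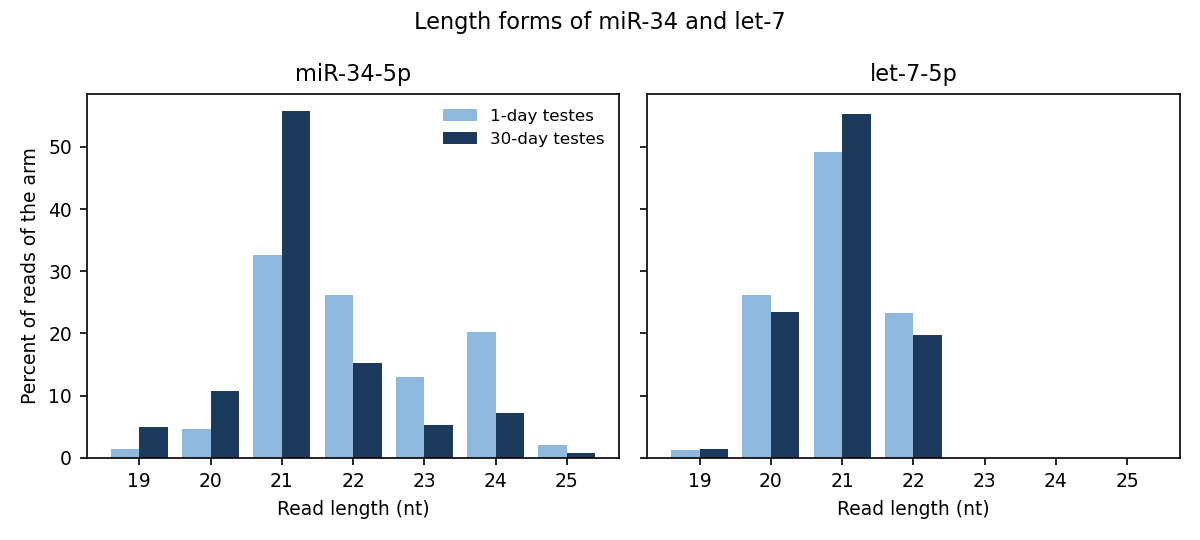
Percent of the reads of an arm (vertical axis) at each read length in nt (horizontal axis), for miR-34-5p (left) and let-7-5p (right), with light bars for the 1-day library and dark bars for the 30-day library. The 21-nt form of miR-34-5p went from 32.6% to 55.8% of its reads, and that of let-7-5p from 49.1% to 55.3%.

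miR-34 shares a cluster with miR-317 and miR-277, and all 3 rose. Their hairpins lie on the plus strand of chromosome 3R in the BDGP6 annotation, mir-317 at 10091126 to 10091217, mir-277 at 10100022 to 10100121 and mir-34 at 10100936 to 10101034. miR-277-3p, known to regulate metabolism, had a ratio of 2.20 (2.11 to 2.31), which was 1.61 and no longer a call on the miRNA scale. The cluster median of 4.62 stood at percentile 99.3. In the cluster of miR-12, miR-283 and miR-304 the ratios were 1.98, 1.74 and 1.55, with the median at percentile 90.9, and of these miR-12-5p was a call on the transposon scale at 2.21. In the pair of miR-275 and miR-305, miR-305-5p rose 2.11-fold, or 1.55-fold and no longer a call on the miRNA scale, and miR-275-3p had a ratio of 1.30, or 0.953 on the miRNA scale.

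The 4 arms that fell were miR-955-5p, miR-980-3p, the miR-974-3p star arm and miR-997-5p. miR-980-3p fell from 351.5 to 45.4 RPM, a ratio of 0.129 (0.118 to 0.142). miR-955-5p fell from 149 to 6 reads, a ratio of 0.0415 (0.0150 to 0.0925). The miR-974-3p star arm had a ratio of 0.344 (0.333 to 0.356). miR-997-5p, with a ratio of 0.498 (0.486 to 0.511), or 0.556 and no longer a call on the transposon scale, belongs to a hairpin that the RefSeq gene table lists as the hairpin RNA gene hpRNA:CR46343. The next smallest ratios were no calls on the main scale, and they were 0.606 for miR-375-3p, 0.607 for the miR-929-5p star arm, 0.612 for miR-2280, 0.642 for the miR-984-3p star arm, 0.661 for miR-958-3p and 0.662 for miR-1013-3p. On the miRNA scale these 6 arms passed the rule, with ratios of 0.443, 0.444, 0.448, 0.470, 0.484 and 0.485 in the same order.

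Clusters of miRNAs known for high expression in testis had ratios below 1 in most members. None of their most abundant arms was a call on the main scale. The miR-974-3p star arm, which fell, belongs to the miR-972 to miR-979 cluster. It is the less abundant arm of its hairpin, so it is not counted below. In the miR-959 to miR-964 cluster 5 of 6 members lay below 1, with miR-962-5p at 0.670, miR-964-5p at 0.777, miR-959-3p at 0.782 and miR-960-5p at 0.827. Its median of 0.804 lay at percentile 0.765, and miR-962-5p passed the rule on the miRNA scale at 0.490. In the miR-972 to miR-979 cluster 5 of 8 members lay below 1, with a median of 0.870 at percentile 1.51. Its members farthest from 1 were miR-973-5p at 0.722, the miR-979-5p star arm at 0.727, miR-976-3p at 0.853, and the miR-975-3p star arm at 1.27, or 0.932 on the miRNA scale. In the X-linked group all 4 ratios lay below 1, with miR-303-5p at 0.729, miR-984-5p at 0.849, the miR-983-3p star arm at 0.864 and miR-982-5p at 0.936, or 1.04 on the transposon scale, and the median of 0.857 lay at percentile 7.24.

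The 5 most abundant miRNAs were miR-8-3p, bantam-3p, miR-34-5p, let-7-5p and miR-31a-5p, which held 46.6% of miRNA reads at 1 day and 52.7% at 30 days. miR-8-3p had a ratio of 1.41 (1.40 to 1.41), miR-31a-5p 1.51 (1.496 to 1.522) and bantam-3p, which promotes growth and survival, 0.955 (0.951 to 0.959), or 1.06 on the transposon scale. In the list of growth and germline miRNAs 1 of 6 members rose, miR-14-3p at 2.04, or 1.49 and no longer a call on the miRNA scale. miR-7-5p in this list was at 0.879 and miR-278-3p at 1.10, or 0.806 on the miRNA scale, and its median of 1.05 (percentile 42.3) was 0.769 on the miRNA scale. In the miR-310 cluster 1 of 6 members rose, miR-310-3p at 2.06, or 1.51 and no longer a call on the miRNA scale. miR-311-3p was at 1.33 and miR-312-3p at 1.10, which were 0.972 and 0.809 on the miRNA scale, the miR-992-5p star arm was at 0.866, and the median of 1.08 (percentile 36.4) was 0.788 on the miRNA scale. In the miR-2 family 1 of 7 measured members rose, the miR-308-5p star arm at 3.32, while miR-13a-3p was at 1.62, miR-11-3p at 1.54 and miR-13b-3p at 1.40, which was also the median (percentile 77.0).

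In the remaining lists most members were within 2-fold. miR-9c, miR-306, miR-79 and miR-9b had ratios from 0.944 to 1.06 and a median of 1.03 (percentile 44.1). All 4 were below 1 on the miRNA scale, with a median of 0.753, and above 1 on the transposon scale, miR-9c-5p at 1.05. Of the mirtrons, miRNAs made by splicing, 6 of 15 were measured, and 1 rose, the miR-1012-5p star arm at 3.42. The miR-1006-5p star arm was at 1.46 and miR-1005-3p at 1.31, or 0.958 on the miRNA scale, and the mirtron median of 1.26 (percentile 45.0) was 0.926 on the miRNA scale. miR-996-3p and miR-279-3p had ratios of 1.30 and 1.13, which were 0.948 and 0.827 on the miRNA scale.

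miRNAs known from other cell types were read at both ages. The muscle miRNAs miR-1-3p and miR-133-3p had ratios of 1.67 (1.65 to 1.69) and 1.63 (1.40 to 1.88). The neural miR-124-3p was at 1.04 (0.919 to 1.19), or 0.764 on the miRNA scale. The sensory organ miRNAs miR-263a-5p and miR-263b-5p were at 1.48 and 1.23, the latter 0.903 on the miRNA scale, and the median of the neural and sensory list, 1.23, lay at percentile 44.4. Of the early embryonic miR-309 cluster miR-3-3p, miR-5-5p and miR-6-3p were measured, with 50 to 78 reads per library and a median ratio of 0.957 at percentile 29.1, and miR-3-3p, which set that median, was at 1.07 on the transposon scale. miR-6-3p was at 1.36, or 0.998 on the miRNA scale.

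Hairpin siRNAs are RNAs of about 21 nt that Dicer-2 makes from long inverted repeats. Reads of 20 to 22 nt from the esi-1, esi-2 and esi-4 loci went from 28160 to 21223 RPM, a ratio of 0.754 (0.750 to 0.758) that was no call. The ratio was 0.620 (0.614 to 0.627) for esi-4, 0.789 (0.784 to 0.795) for esi-2 and 0.832 (0.824 to 0.841) for esi-1, and on the miRNA scale esi-4 passed the rule at 0.454. The guide strand of esi-4.1 gave most of the esi-4 reads, 89150 at 1 day and 53283 at 30 days. Of 50 siRNA names with at least 100 reads 39 had ratios below 1, in 28 of them with an interval below 1, and none was called on the main scale. These names include the bare locus names esi-1, esi-2 and esi-4, which name no single siRNA. Reads with those names had ratios of 0.771, 0.743 and 0.746, all with intervals below 1. By the RefSeq gene table esi-1 is hpRNA:CR18854, at 9787294 to 9790745 on chromosome 2L, and esi-2 is hpRNA:CR46342, at 4921677 to 4928133 on chromosome X.

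Transposon families matched by piRNA-length reads rarely passed 2-fold. Of 105 families with at least 1000 reads of 23 to 28 nt none was higher and 1 was lower, Transib5, from 1075 to 511 reads, at 0.490 (0.440 to 0.545). Transib5 was no call on the transposon scale, at 0.547, or with each distinct sequence counted once, at 0.700. The median family ratio was 0.998, with 53 families below 1 and 99 within 1.5-fold of 1. On the miRNA scale 4 families were lower, and on the transposon scale, which shifted every log2 ratio by 0.16, none was. Summed over all families, reads of this length went from 454093 to 407231 RPM, a ratio of 0.897 (0.896 to 0.898). The 3 most abundant families were PROTOP, a DNA element counted with the FlyBase element hoppel, at 0.776 (0.773 to 0.778), baggins, a LINE, at 0.897 (0.894 to 0.900), and NINJA at 0.634 (0.631 to 0.637). baggins came to 1.0001 on the transposon scale and to 1.01 with distinct sequences counted once, and NINJA passed the rule on the miRNA scale at 0.464.

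**Figure D4:**
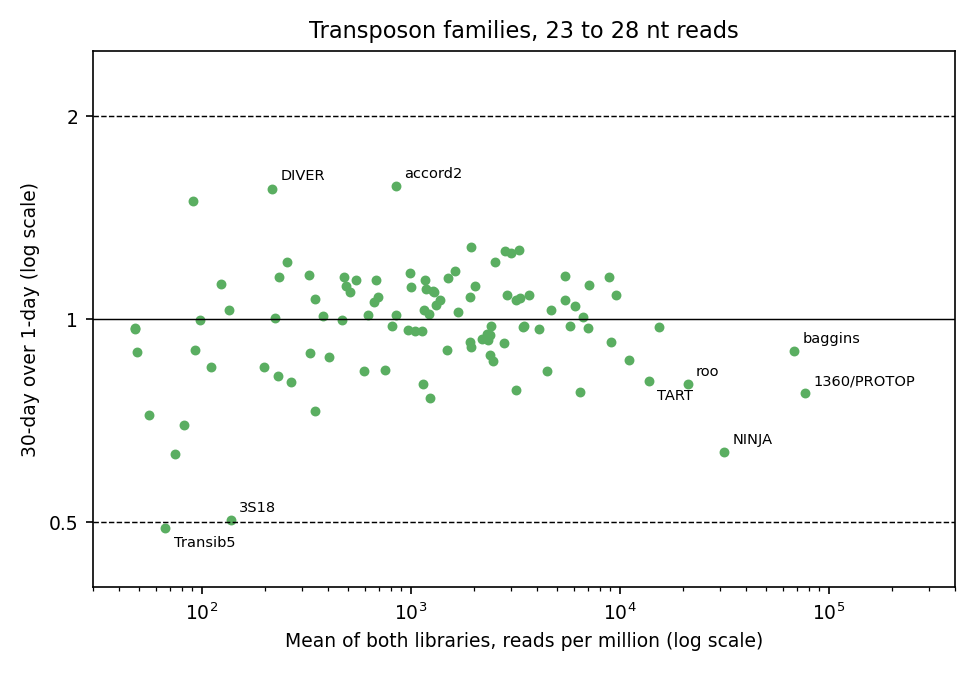
Ratio of 30-day to 1-day RPM (vertical axis, log scale) against the mean of both libraries in RPM (horizontal axis, log scale) for the 105 transposon families, 1 point per family, reads of 23 to 28 nt, with a line at 1 and dashed lines at 2-fold. All points but Transib5 at 0.490 lie between the dashed lines on this scale, and the abundant families NINJA at 0.634 and PROTOP at 0.776 lie below 1.

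The remaining families with small ratios were 3S18 at 0.503, LINEJ1 at 0.630 and G4 at 0.696, and on the miRNA scale 3S18 and LINEJ1 passed the rule at 0.368 and 0.461. The largest ratios were 1.57 (1.53 to 1.62) for accord2, 1.56 for DIVER and 1.49 for Gypsy7, and 1.28 for max-element and 1.27 for gypsy6, which were 0.935 and 0.926 on the miRNA scale. Some gypsy-group elements are active in somatic cells of the ovary. Those in the gypsy-group list had 20 of 27 ratios above 1 and a median of 1.08 (percentile 96.2), or 0.790 on the miRNA scale. Among them gypsy2 was at 1.26, or 0.923 on the miRNA scale. The telomere elements TART, HeT-A and TAHRE were at 0.809, 0.806 and 0.898, with the median at percentile 10.9, and TAHRE came to 1.002 on the transposon scale. Other LINE elements had 16 of 25 ratios below 1 and a median of 0.968 (percentile 8.26), or 1.08 on the transposon scale, with BS at 0.730, G at 0.763 and G6 at 0.801. The list fixed as Copia and BEL elements had 10 ratios on each side of 1 and a median of 0.993 (percentile 49.9). That median was 1.11 on the transposon scale, and rooA in this list was at 0.779. The list also holds mdg3, micropia, Circe and invader families, which are gypsy-group elements. Its values are therefore not those of Copia and BEL elements alone, and the gypsy-group list is not complete. DNA elements had a median of 1.003 (percentile 38.5), or 0.734 on the miRNA scale, with hobo at 0.839, FB at 0.891 and pogo at 1.15, or 0.844 on the miRNA scale.

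Suppressor of Stellate repeats, Su(Ste), are a main source of testis piRNAs and silence the Stellate genes. Their reads of 23 to 28 nt went from 9506 to 8653 RPM, a ratio of 0.910 (0.903 to 0.918) that was no call and was 1.015 on the transposon scale. The 7 repeat copies with at least 1000 reads had ratios from 0.844 to 1.08, and reads shared by these near-identical copies are uncertain in their source. Reads of this length named for Stellate had a ratio of 0.891 (0.862 to 0.921), and those named for vas, a germline gene matched by testis piRNAs, 0.723 (0.680 to 0.769). The piRNA clusters flamenco, 42AB, 38C, 20A, 80EF and AT-chX were not analysed here.

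Reads that carry the names of upd1, Imp, Stat92E, shg, bam and esg were few, while tj, Dcr-2 and AGO2 had 8140, 3128 and 3023 over both libraries. As RNAs of 19 to 28 nt, none of these reads measure mRNA level. They were also not of a single kind. Reads of 23 to 28 nt were 97.0% for tj, 90.2% for upd1, 76.2% for Stat92E and 72.5% for Dcr-2. They were 67.1% for shg, 48.7% for Imp and 8.63% for AGO2. upd1, the signal sent by the hub cells of the niche (X, 18305354 to 18309291), had 27 reads at 1 day and 24 at 30 days, a ratio of 0.917 (0.506 to 1.65), or 1.02 on the transposon scale, so a difference was not detectable at this depth. Imp (X, 10787869 to 10824277) rose from 64 to 314 reads, a ratio of 5.06 (3.86 to 6.73). Between the same libraries 8 cytoskeletal and translation housekeeping genes had a summed ratio of 2.53 (2.41 to 2.66), with 7 of the 8 higher. On the miRNA scale these genes summed to 1.85, with 1 of the 8 higher, and Imp was at 3.70. Stat92E, the transcription factor downstream of upd1, had a ratio of 1.45 (1.16 to 1.81), and shg, which encodes E-cadherin, 1.78 (1.27 to 2.501). tj, whose transcript makes piRNAs in somatic gonad cells, was at 1.06 (1.01 to 1.11), or 0.774 on the miRNA scale. Of the siRNA pathway genes AGO2 was at 1.26 (1.18 to 1.36), or 0.925 on the miRNA scale, and Dcr-2 at 0.768 (0.715 to 0.825). bam had 17 and 12 reads and esg 5 and 7. upd3 had 1 and 11 reads, a ratio of 11.3 (1.65 to 488), and upd2 had 0 and 3, too few for a ratio.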

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

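The tests of miR-1 against miR-124, accessory gland genes, larval fat body genes and all transcript reads were chosen after part of the results had been seen, and the ribosomal protein test before its result was seen. Marker lists were written after part of the values had been seen, and how many of their genes the testis also expresses was not counted. Reads named for mRNAs lie outside the small RNA comparison and exceeded the 3 counts that a count of 0 allows. They were searched among 885 genes with at least 300 such reads, less than 70% of them of piRNA length and less than 20% in 1 sequence. The lowest 30-day to 1-day ratios were those of Fbp1 (1974 reads at 1 day, 4 at 30 days), Lsp2 (1066 and 154) and Mhc (598 and 113). The highest were those of Arc1 (1142 reads at 30 days, 36 at 1 day), CG12506 (426 and 21) and CG5612 (301 and 16). Reads with no name numbered 105457 at 1 day and 100668 at 30 days and exceeded the same limit.

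Larval fat body transcripts stood out in the 1-day library. Fbp1, Fbp2, Lsp1alpha, Lsp1beta, Lsp1gamma and Lsp2 summed to 3593 reads at 1 day and 179 at 30 days, a ratio of 0.0514 (95% interval 0.0440 to 0.0597). A general loss of mRNA-named reads at 30 days was set against the ratio of all transcript reads, 0.985 (0.983 to 0.988). At 1 day 426066 of these 1247135 reads were of 21 nt and 662980 were of piRNA length. The sum therefore cannot exclude a loss of mRNA fragments. The 8 housekeeping genes, at 2.53 and at 1.85 on the miRNA scale, argue against a loss of all mRNA fragments alike. Larval fat body cells carried into the 1-day dissection are a candidate source, since 6 of the 6 list genes were at least 2-fold lower at 30 days, in a list written after the first of these genes had been seen. Age itself stays open, untested, because larval fat body cells are known to persist in newly emerged adults.

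Of the 885 genes 91 were higher at 30 days, Arc1 and Imp among them, and 5 were lower. On the miRNA scale 44 were higher and 48 lower, so that more genes rose than fell depends on the scale. Fewer germline cells with every other cell type raised alike would raise miR-1 and miR-124 alike, and their ratios differ by a factor of 1.60 (1.41 to 1.82). But muscle miRNAs and muscle mRNAs went opposite ways, miR-1-3p at 1.67 and Mhc at 0.195. Whether miR-1 tracks muscle content here is thus unknown, and this test cannot decide. The mRNA marker lists went apart. They cannot decide on a like rise of all other cell types, because reads of this length do not measure mRNA level. Expression of marker genes can also change within the same cells. Midgut enzyme genes were at 11.5 (8.54 to 15.8), led by Amy-d with 26 and 345 reads. Flight muscle genes were at 0.118 (0.0826 to 0.165), led by Act88F with 158 and 13 reads. Accessory gland genes had a summed ratio of 0.737 (0.520 to 1.04), from 84 and 60 reads, which gives no sign of more accessory gland tissue at 30 days. More breakdown of mRNA in the 30-day sample stays open. Its test asked only whether ribosomal protein genes share the rise to be explained, so other causes of that rise would pass it too. The median log2 ratio over 78 ribosomal protein genes was 0.61, although 15 of them were called higher and 1 lower and their summed ratio was 1.36 (1.32 to 1.39). On the miRNA scale that median was 0.16, the summed ratio 0.992 and the calls 1 higher and 2 lower, so the result of this test depends on the scale too. Structural RNA reads also had a ratio above 1, at 1.78 (1.76 to 1.80), or 1.30 on the miRNA scale, and rRNA pseudogene reads had one below 1, at 0.854 (0.850 to 0.858), and neither was used as a test. The 6 larval fat body genes and 4 of the 5 flight muscle genes fell, so breakdown of all mRNAs alike is not the only difference between the libraries. A tissue with less share at 30 days would lower its genes at any rate of breakdown. These genes therefore cannot decide whether breakdown rose. The median log2 ratio over the 885 genes was -0.10 (0.06 on the transposon scale). That set still holds genes with siRNA-type and piRNA-type reads, so its median cannot decide either. For gut tissue in the 30-day sample no test was set, although 4 of the 7 midgut genes read were higher and 0 lower on each scale. alphaTry among them, with 0 reads at 1 day and 21 at 30 days, had no ratio and could not be called. Age itself stays open, untested, and with 1 library per age a difference between preparations cannot be separated from age.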

How the results depend on the processing

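The deposited arm names, the leaving out of rRNA pseudogenes, the transposon scale for miRNAs, hairpin siRNAs and Su(Ste) and both scales for single genes, read classes and transposon reads of 21 nt were chosen after seeing the data, and the remaining alternatives were planned. Each age has 1 library, so any effect of the preparation lies outside every interval. All genome-matching reads and all reads of the tables could not be told apart and are given as 1 alternative. Transposon reads of a single family or a single genome place were not run, because each sequence carries 1 name and no position. No paired analysis was possible because each age has 1 library of pooled males. Denominators change ratios by their own factor, and for the other alternatives that changed a value the cause was not tested. Depth limits what can be said of upd1, with 51 reads over both libraries.

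The let-7 ratio of 1.91 was 1.40 on the miRNA scale, 1.47 with TMM and 2.13 on the transposon scale, and stayed within its interval under the other 5 alternatives. Higher miRNA arms went from 48 to 25 on the miRNA scale and 28 with TMM, all among the 48, and to 29 with a minimum of 1000 reads, which tests 112 arms. Lower arms went from 4 to 11 on the miRNA scale and 8 with TMM. On the transposon scale 55 arms were higher and 3 lower. Higher transposon families went from 0 to 1 with a minimum of 100 reads (R2, named after its value was seen, 52 and 140 reads). Lower families went from 1 to 4 on the miRNA scale, 0 on the transposon scale, 2 with a minimum of 100 reads and 0 with distinct sequences. The hairpin siRNA ratio of 0.754 was 0.552 on the miRNA scale, 0.840 on the transposon scale and 0.723 at 21 nt. The Su(Ste) ratio of 0.910 was 0.666 on the miRNA scale and reversed to 1.015 on the transposon scale. The piRNA-length share at 1 day was 52.3% at 24 to 27 nt, 68.91% with structural RNA kept in and 76.0% without miRNA reads, and at 30 days 48.2%, 65.66% and 77.7%. The difference of -3.24 points was -4.17 at 24 to 27 nt and reversed to 1.64 without miRNA reads.

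Of 746 alternative values for 107 named items, 471 stayed within the counting interval of the main value, 246 moved out of it and 29 reversed from an interval that excluded 1. Of the 246, 7 also crossed 1, from intervals that held 1. On the miRNA scale the reversed ratios were 0.958 for miR-1005-3p, 0.903 for miR-263b-5p, 0.953 for miR-275-3p, 0.806 for miR-278-3p, 0.827 for miR-279-3p, 0.972 for miR-311-3p, 0.809 for miR-312-3p, 0.932 for miR-975-3p star, 0.948 for miR-996-3p, 0.779 for miR-9b-5p, 0.923 for gypsy2, 0.926 for gypsy6, 0.935 for max-element, 0.844 for pogo, 0.774 for tj and 0.925 for AGO2. With TMM they were 0.951 for miR-263b-5p, 0.848 for miR-278-3p, 0.870 for miR-279-3p, 0.851 for miR-312-3p, 0.981 for miR-975-3p star, 0.997 for miR-996-3p and 0.819 for miR-9b-5p. On the transposon scale TAHRE came to 1.002, baggins to 1.0001, bantam-3p to 1.06, miR-982-5p to 1.04 and miR-9c-5p to 1.05, and with distinct sequences baggins came to 1.01.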

Other observations

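The test of transposon and Su(Ste) read length was chosen after part of the lengths had been seen, and the test of the remaining miRNA arms before its result was seen. miR-34 reads were shorter at 30 days, and a small group of miRNAs went with it. The mean length of miR-34-5p changed by -0.838 nt. Of 112 arms with at least 1000 reads 7 were shorter by at least 0.4 nt and 0 were longer by as much, and the 7 were miR-34-5p, miR-31b-5p, miR-31a-5p, miR-263b-5p, miR-274-5p, miR-986-5p and miR-317-3p. A general shift of the library is argued against by the median change over the remaining 111 arms, 0.0093 nt. A size selection for shorter RNA is argued against by transposon reads of 23 to 28 nt, whose mean length changed by 0.101 nt, and by Su(Ste) reads, by 0.159 nt. Stronger trimming of the 3′ ends of some miRNAs at 30 days may explain the pattern and was not tested, and neither was a different mix of cells, so both stay open, as does age itself.

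Star arms gained on their partners in many hairpins. Of 55 hairpins with both arms at 100 reads or more the star arm gained in 38, with a median log2 gain of 0.22 (quartiles -0.13 and 0.70). The star label is that of the deposited names, and in some of these hairpins it marks the more abundant arm. Among these the star share went from 97.0% to 98.7% in miR-284 and from 96.6% to 92.2% in miR-92a. The star share of the hairpin's reads went from 0.915% to 2.66% in bantam and from 32.3% to 60.6% in miR-100, and from 42.2% to 22.6% in miR-974 and from 0.351% to 0.174% in miR-34. Transposon reads of 21 nt, the length of siRNAs, had a ratio of 0.740 (95% interval 0.737 to 0.743), against 0.897 for reads of 23 to 28 nt, and 52 of 62 families had the lower ratio at 21 nt. Of these roo went from 164100 to 107337 reads of 21 nt and NOMAD from 123089 to 80746, ratios of 0.674 (0.669 to 0.680) and 0.676 (0.670 to 0.682) that were no calls and were 0.494 and 0.495, both called lower, on the miRNA scale.

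Spermatid genes, whose mRNAs are stored in late germ cells, had a summed ratio of 2.70 (2.49 to 2.93) in mRNA-named reads, with 8 of 9 genes higher, and of 1.98 on the miRNA scale, with 2 of 9 higher. In the same libraries the housekeeping genes summed to 2.53 (2.41 to 2.66) and ribosomal protein genes to 1.36 (1.32 to 1.39), or 1.85 and 0.992 on the miRNA scale. Germline genes had a ratio of 0.783 (0.744 to 0.824), which rests on vas, with 2755 and 1914 reads, 90.7% of them of piRNA length. The 8 germline genes without vas had 691 and 703 reads, a ratio of 1.05 (0.943 to 1.17), or 0.768 on the miRNA scale. Adult fat body and blood plasma genes went both ways, with a summed ratio of 1.06 (0.941 to 1.20), or 0.777 on the miRNA scale, Tsf1 from 23 to 383 reads and Rfabg from 499 to 118. Blood cell genes also went both ways, with Pxn at 2.03 (1.48 to 2.81), or 1.48 and no longer a call on the miRNA scale, and Hml at 0.492 (0.313 to 0.761), or 0.549 and no longer a call on the transposon scale. They summed to 1.38 (1.16 to 1.64), or 1.01 on the miRNA scale. Neural genes summed to 1.00 (0.621 to 1.62), or 0.735 on the miRNA scale, from 38 and 37 reads. Among them Syt1, with 9 and 1 reads, was called lower at 0.115 (0.00261 to 0.827). In contrast para, with 11 and 21 reads, was at 1.97 (0.907 to 4.52), or 2.20 and a call on the transposon scale.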
